A study of Arabidopsis thaliana with 12 samples.

How the data were processed

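RNA was sequenced from the aboveground parts of Arabidopsis thaliana Col-0 plants grown in boxes. Per the labels' protocols, 4-week-old plants were sprayed with 200 µL per box of buffer (mock) or of 1 of 3 bacterial suspensions at 20000000 CFU/mL, and were collected 96 h later. The bacteria were Pst, Williamsia sp. Leaf354 and Microbacterium sp. Leaf347, named Williamsia and Microbacterium from here on. The labels call the Pst plants infected and the other bacterial plants inoculated, and they do not expand the abbreviation Pst. Each box held 4 plants, and 2 plants from different boxes were pooled for each replicate. The design has 4 groups with 3 replicates each, 12 libraries in all. Per the labels' protocols, libraries were made from polyadenylated RNA with a kit that keeps no strand information, and were sequenced as paired-end reads.

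The deposited table holds counts, whole numbers of reads per gene for 32833 genes and the 12 libraries, with no normalization. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1 and assigned to TAIR10 gene models with featureCounts 1.22.2. The aligner and the strand setting of the read assignment are not given in the sources used here. Gene symbols were taken from a TAIR10.1 annotation by locus identifier, which matched 32548 of the 32833 identifiers. The 285 unmatched identifiers are organelle loci. No coordinates are printed, because the annotation release of the reference differs in version from that named for the counts.

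Totals per library were between 19806741 and 21570299 counts. A count of 0 in a library allows up to 0.139 to 0.151 CPM (counts scaled to the library total), the size of 3 counts at these totals, and this floor covers counting error only. Each p-value measures the spread between pooled-plant samples of a group. The labels do not state which boxes supplied each replicate, so replicates of a group may share boxes. The sample titles place all libraries in experiment 1, so spread between experiments is not covered.

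Group was the only factor, and no pairing was used, since the labels do not say that replicate numbers link libraries of different groups. All 12 libraries were fitted together in R 4.3.3 with edgeR 4.0.16. Scaling was by trimmed mean of M-values (TMM), genes with low counts were removed by the default expression filter of edgeR, and a quasi-likelihood model with 1 coefficient per group left 8 residual degrees of freedom. The filter kept 19190 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over all genes tested within a comparison. The standard error (SE) of a log2 fold change was derived from the quasi-likelihood test of that gene. Each bacterial treatment was compared with mock, and the bacterial treatments were compared directly with each other, which made 6 comparisons. A further test asked which genes differed among the 4 groups. Values per library are CPM after TMM scaling.

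The study's groups, the comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those named below as later choices. The 26 lists held 428 gene memberships, of which 389 could be tested, and 1 member was not in the table. They cover defence signalling and metabolites, hormones, nutrient status, photosynthesis, stress, senescence and cell division, with further lists as checks of harvest time, handling and tissue. The 25 lists with at least 2 tested genes were each tested in the 6 comparisons with camera from limma 3.58.1, at a preset correlation between genes of 0.01. The 150 p-values were adjusted together. Camera asks whether a list moved relative to the other genes. It was repeated with the correlation between genes estimated for each list. Fry, which tests whether a list's genes move one way (directional) or in either direction (mixed), was run as an alternative.

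Named genes were chosen by a rule with 5 parts. They were the 10 highest and the 10 lowest called fold changes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries. For each list, they were the 2 called members with the smallest p-values. Then came 11 fixed defence markers, genes with opposite calls in 2 comparisons with mock, and the 10 genes called the same way in all 3 comparisons with mock whose smallest absolute log2 fold change was largest. Genes outside this rule were chosen after their values were seen, and the text says so.

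Similarity between responses was the Pearson correlation, across genes, of the log2 fold changes of 2 treatments against mock. Genes are not independent replicates, and its error is a jackknife over the 12 libraries. Comparisons that share a control correlate even without a response. The size of this effect was measured in 20 sets of simulated counts in which every library was drawn from the mock means, and in 100 draws of residuals dealt at random among the libraries.

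The alternatives were relative log expression (RLE) and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, removal of organelle genes, a fit of only the 2 groups compared, an absolute log2 fold change of at least 1, and leaving out each library in turn. A fit with 1 surrogate variable (sva 3.50.0) was added after the data were seen. The calling was tested on simulated data with the replicate numbers of the study. Of 100 genes changed 2-fold, up or down at random, 68% were recovered. Of 100 changed 4-fold in the same way, 91% were recovered, and 6 of the 165 calls were false. In a separate draw of simulated counts camera called a list raised 1.5-fold and 0 of 20 random lists. Genes were drawn independently there, so that draw cannot show how camera behaves where the genes of a list correlate.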

Results

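Counts per gene were compared between mock plants and plants treated with Pst, Williamsia or Microbacterium, each with 3 replicates of 2 pooled plants collected 96 h after treatment. Library totals lay between 20045897 and 21570299 counts in mock, between 19806741 and 21193928 in Pst, between 19852375 and 20836350 in Williamsia, and between 21071438 and 21529936 in Microbacterium. The 10 most abundant genes took 9.43 ± 0.27% of counts in mock and 10.1 ± 0.28% in Pst (mean ± SD, n = 3). Replicates of a group differed by more than counting error, with a chi-square per degree of freedom between 8.12 and 23.8 over 12 replicate pairs. Of 19190 genes tested, 1657 differed among the 4 groups by edgeR (4253 at an unadjusted p under 0.05, 2520 by DESeq2 and 1579 by limma-voom). That edgeR count was 940 without mock replicate 1, 990 without mock replicate 3 and 1075 without Pst replicate 1.

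The comparison of Pst with mock asked how the aboveground transcriptome differed 96 h after infection. AT1G80440 (KMD1 in the annotation) was 29.7-fold higher in Pst, at 136.6 ± 56.4 CPM against 4.63 ± 2.71 CPM (mean ± SD, n = 3), a log2 fold change of 4.89 ± 0.40 (SE). TPS8 (AT1G70290), a gene of the trehalose-phosphate synthase family, rose by 4.48 ± 0.28, from 13.4 ± 2.42 to 298.3 ± 122 CPM. BBX14 (AT1G68520), a B-box transcription factor gene, rose by 4.53 ± 0.25, from 18.1 ± 2.47 to 418.3 ± 107 CPM. AT3G62950, AT5G61590 (DEWAX), AT1G02610, AT3G15450, BT2 (AT3G48360), ATCTH (AT2G25900) and BBX17 (AT1G49130) complete the 10 highest log2 fold changes, which reach down to 3.99, among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries. Within the same limits the lowest value was that of AT1G24580, which fell by 3.88 on the log2 scale (SE 0.44), from 34.7 ± 15.6 to 2.35 ± 1.45 CPM. RHA2A (AT1G15100), a RING-finger gene, fell from 91.2 ± 9.10 to 14.0 ± 4.30 CPM (log2 fold change -2.70 ± 0.22). BBX32 (AT3G21150), whose model overlaps a gene on the same strand, fell by 3.00 on the log2 scale (SE 0.32). The selection itself requires that in each of these genes all 3 Pst libraries lie on 1 side of all 3 mock libraries. EdgeR called 3068 genes, 1457 higher and 1611 lower in Pst, and 5687 genes had an unadjusted p under 0.05. Of the called genes, 640 changed by at least 2-fold, 412 of them higher. A fit of only the Pst and mock libraries called 1928 genes.

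Of 11 fixed defence markers, 10 did not pass in Pst, with edgeR adjusted p-values between 0.114 and 0.877. PR1 (AT2G14610) had a log2 fold change of -0.89 ± 0.41 (SE, n = 3 per group), at 74.1 ± 19.7 CPM against 137.6 ± 45.4 CPM in mock. PR2 (AT3G57260) was at 0.11 ± 0.37, PR5 (AT1G75040) at 0.48 ± 0.33, ICS1 (AT1G74710) at 0.21 ± 0.40 and PAD3 (AT3G26830) at 0.30 ± 0.60. FMO1 (AT1G19250), CYP71A12 (AT2G30750), FRK1 (AT2G19190) and PDF1.2a (AT5G44420) did not pass either, and FRK1 overlaps a gene with more reads. VSP2 (AT5G24770) passed only without mock replicate 3 (adjusted p = 0.0386). The marker that passed, LOX2 (AT3G45140), rose by 0.91 ± 0.26, and its adjusted p was 0.134 without mock replicate 1, 0.115 without mock replicate 2, 0.0617, 0.106 and 0.0565 without Pst replicates 1, 2 and 3, and 0.0515 without Microbacterium replicate 1. Among 25 tested salicylic acid and systemic acquired resistance genes, 3 were higher, 0 lower and 22 did not pass, with 5 called when adjusted over the list alone. NPR4 (AT4G19660) rose by 1.15 ± 0.18. NPR1 (AT1G64280) rose by 0.44 ± 0.12, with adjusted p-values of 0.103, 0.0782, 0.127 and 0.104 without mock replicates 1 and 3 and Pst replicates 1 and 2. Camera did not call the salicylic acid list (adjusted p = 0.431, median log2 fold change 0.21). Its mean deviation from the group mean ran from -0.846 to 0.638 among the Pst libraries and from -0.119 to 0.209 in mock (log2 CPM). With that spread, the absence of a call does not show that the list was unchanged.

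Of 30 tested genes of the jasmonic acid list, 11 were higher in Pst than in mock, 1 was lower and 18 did not pass, with 16 called when adjusted over the list alone. AOC2 (AT3G25770) rose by 1.95 ± 0.40 and AOC1 (AT3G25760) by 1.53 ± 0.32 (SE, n = 3 per group). Both encode allene oxide cyclases of jasmonate synthesis and were chosen after their values were seen. JAZ7 (AT2G34600) rose by 2.06 ± 0.38 and JAZ3 (AT3G17860) by 0.61 ± 0.11, and both encode repressors of the jasmonate response. The gene that fell, JAR1 (AT2G46370), also named after its value was seen, changed by -0.35 ± 0.078. The list's median log2 fold change was 0.91 and camera placed it up (adjusted p = 2.08e-06), while adjusted p = 0.951 with an estimated correlation. The mean of the list lay between -0.07 and 0.62 in the Pst libraries (log2 CPM centred per gene), at -0.75 and -0.99 in mock replicates 1 and 2, and at 0.19 in mock replicate 3, so 2 of 3 Pst libraries lay above all mock libraries. MYC2 is listed at 0 in all 12 libraries, and its model overlaps another gene.

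Of 43 tested nuclear-encoded photosynthesis genes, 19 were higher in Pst, 0 lower and 24 did not pass, with 30 called when adjusted over the list alone. PSAD2 (AT1G03130) rose by 0.77 ± 0.098, from 732.1 ± 52.4 to 1249 ± 110 CPM, and LHCB2.3 (AT3G27690) rose by 0.67 ± 0.11 (SE, n = 3 per group). Both models overlap a neighbouring gene with fewer reads. The median log2 fold change of the photosynthesis list was 0.28, and camera placed it up (adjusted p = 6.63e-11), with adjusted p = 0.951 with an estimated correlation. All 3 Pst libraries had a higher mean of the list than all 3 mock libraries. Reads of near-identical family members, such as the LHCB and RBCS genes, cannot be assigned to 1 gene with certainty. In the iron homeostasis list BTS (AT3G18290) rose by 1.24 ± 0.16 and OPT3 (AT4G16370) by 0.96 ± 0.19. Of its 15 tested genes, 4 were higher, 0 lower and 11 did not pass, with 4 called when adjusted over the list alone. Camera placed the iron list up (adjusted p = 0.00836, median 0.77), with adjusted p = 0.951 with an estimated correlation, and all 3 Pst libraries had a higher mean of the list than all 3 mock libraries.

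**Figure D1:**
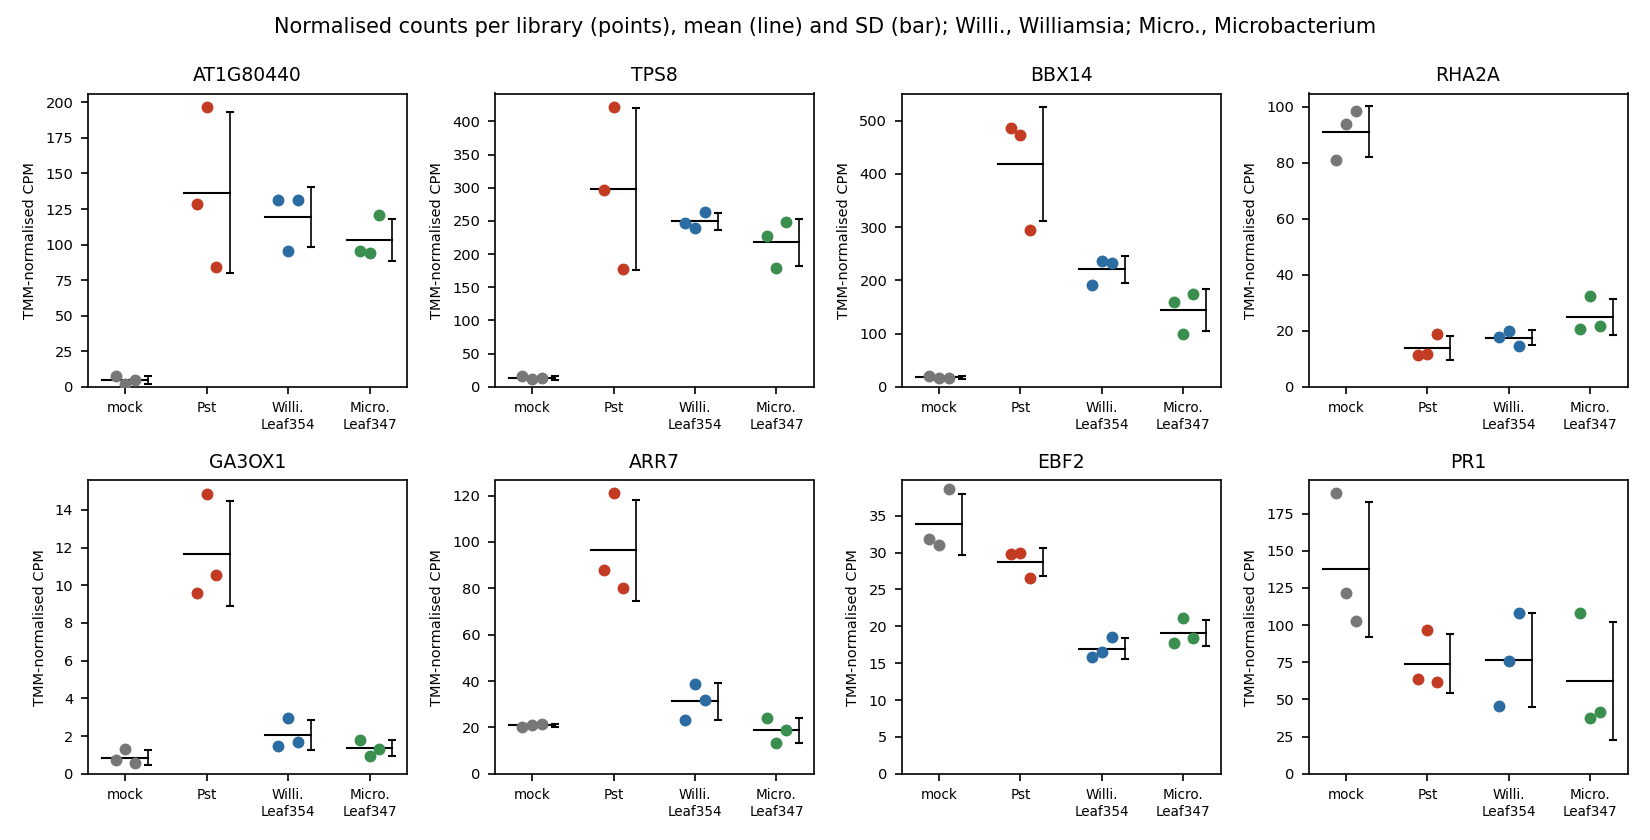
CPM per library of 8 genes in mock, Pst, Williamsia and Microbacterium, with points for libraries, lines for group means and bars for the SD (n = 3). AT1G80440 lies at a mean of 4.63 CPM in mock and 136.6 CPM in Pst, while PR1 lies at 137.6 CPM in mock and 74.1 CPM in Pst and did not pass.

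Most abscisic acid and dehydration genes called in Pst were lower, in a list where mock replicate 2 stood apart. HAB1 (AT1G72770), a protein phosphatase gene of abscisic acid signalling, changed by -0.78 ± 0.15, and HB-12 (AT3G61890) by -1.11 ± 0.20 (SE, n = 3 per group). HAI2 (AT1G07430), another such phosphatase gene, fell from 13.4 ± 12.5 to 1.58 ± 0.55 CPM. Of 22 tested genes, 1 was higher, 7 were lower and 14 did not pass, with 9 called when adjusted over the list alone. Camera gave an adjusted p of 0.12 for this list at a median log2 fold change of -0.52. The mean of the list (log2 CPM centred per gene) was 0.95 in mock replicate 2 and 0.02 and -0.17 in mock replicates 1 and 3, and mock replicate 3 lay below Pst replicates 2 (-0.07) and 3 (-0.15). HAI2 was at 27.8 CPM in mock replicate 2 and at 7.58 and 4.94 CPM in the others, and its log2 fold change was -3.08, or -1.98 without mock replicate 2 (adjusted p = 0.006). HAI1 (AT5G59220) was not called without mock replicate 2 (adjusted p = 0.0551) or Pst replicate 1 (0.0658). IAA1 (AT4G14560), 1 of 8 auxin response genes and the only one called, rose 4.28-fold, from 6.93 ± 1.24 to 29.6 ± 7.57 CPM (camera adjusted p = 0.0597). In the ethylene list ERF2 (AT5G47220) rose by 1.81 ± 0.34 and EBF1 (AT2G25490) fell by 1.34 on the log2 scale (SE 0.15), with 15 of 17 tested genes not passing. CYP81F2 (AT5G57220) rose by 1.91 ± 0.41, 1 of 2 called among 11 indole glucosinolate genes (camera adjusted p = 0.114). GGP1 (AT4G30530) rose by 0.68 ± 0.15, and the camalexin and 4-hydroxyindole-3-carbonylnitrile list had 3 genes higher and 1 lower of 12 (adjusted p = 0.114). CRK2 (AT1G70520) rose from 22.1 ± 3.08 to 50.7 ± 12.5 CPM, while 2 cysteine-rich receptor-like kinase genes were lower and 25 of 28 did not pass. The median of that list was 0.07 although camera placed it down (adjusted p = 0.944).

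The remaining lists of the comparison of Pst with mock had between 0 and 3 genes called, except the clock list with 6 of 13. GSTF8 (AT2G47730), 1 of 12 oxidative and xenobiotic stress genes, rose by 0.72 ± 0.13 (SE, n = 3 per group). Of 10 phosphate starvation genes 2 were higher and 1 was lower, with SQD2 (AT5G01220) at 1.45 ± 0.37. Its adjusted p reached 0.0769 among the fits without mock replicate 1, mock replicate 2 or Pst replicate 2. The gene that fell, SPX1 (AT5G20150), was not called without mock replicates 1 and 3 (0.0641 and 0.085) or Pst replicates 1 and 3 (0.112 and 0.0822). Of 23 cell division genes 2 were higher, RNR2A (AT3G23580) and TSO2 (AT3G27060), and both overlap genes with more reads. TSO2 was not called without mock replicates 1 and 3 (adjusted p = 0.106 and 0.119), Pst replicates 1 and 3 (0.146 and 0.118), Williamsia replicate 2 (0.0512) or Microbacterium replicate 2 (0.0516). EdgeR called 0 genes in 9 lists, 104 genes in all, of which 17 had an unadjusted p under 0.05. DESeq2 called 4 of them and limma-voom called 1. These were the lists for pathogenesis-related and antimicrobial proteins (14 genes), pattern recognition and early pattern-triggered immunity (28), aliphatic glucosinolates (14), nitrogen assimilation (8), protein folding in the endoplasmic reticulum (10), senescence (9), heat shock proteins (8), root markers (3) and vascular markers (10). Of 8 guard cell markers 1 was lower, FAMA (AT3G24140), and of 8 epidermis markers 1 was higher and 1 lower, CER6 (AT1G68530) at 0.70 ± 0.088 and PDF2 (AT4G04890) at -0.29. FAMA was not called without mock replicate 3 (0.0809) or Pst replicates 1 and 2 (0.066 and 0.0625), nor PDF2 without mock replicate 1 (0.0649) or Pst replicate 2 (0.0804). None of 9 flower markers passed the filter on low counts, so that list was not tested. In the clock list LHY (AT1G01060) changed by -0.50 ± 0.069 and PRR9 (AT2G46790) by -1.37 ± 0.19. Of 13 clock genes 2 were higher and 4 lower, with 7 called when adjusted over the list alone. Camera placed the clock list down (adjusted p = 0.0448, median -0.43), with adjusted p = 0.951 with an estimated correlation. That camera value was 0.0576 and 0.0984 without mock replicates 1 and 3, 0.0775 and 0.057 without Pst replicates 1 and 2, 0.0517 without Williamsia replicate 3, and 0.0589 and 0.0553 without Microbacterium replicates 1 and 3.

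**Figure D2:**
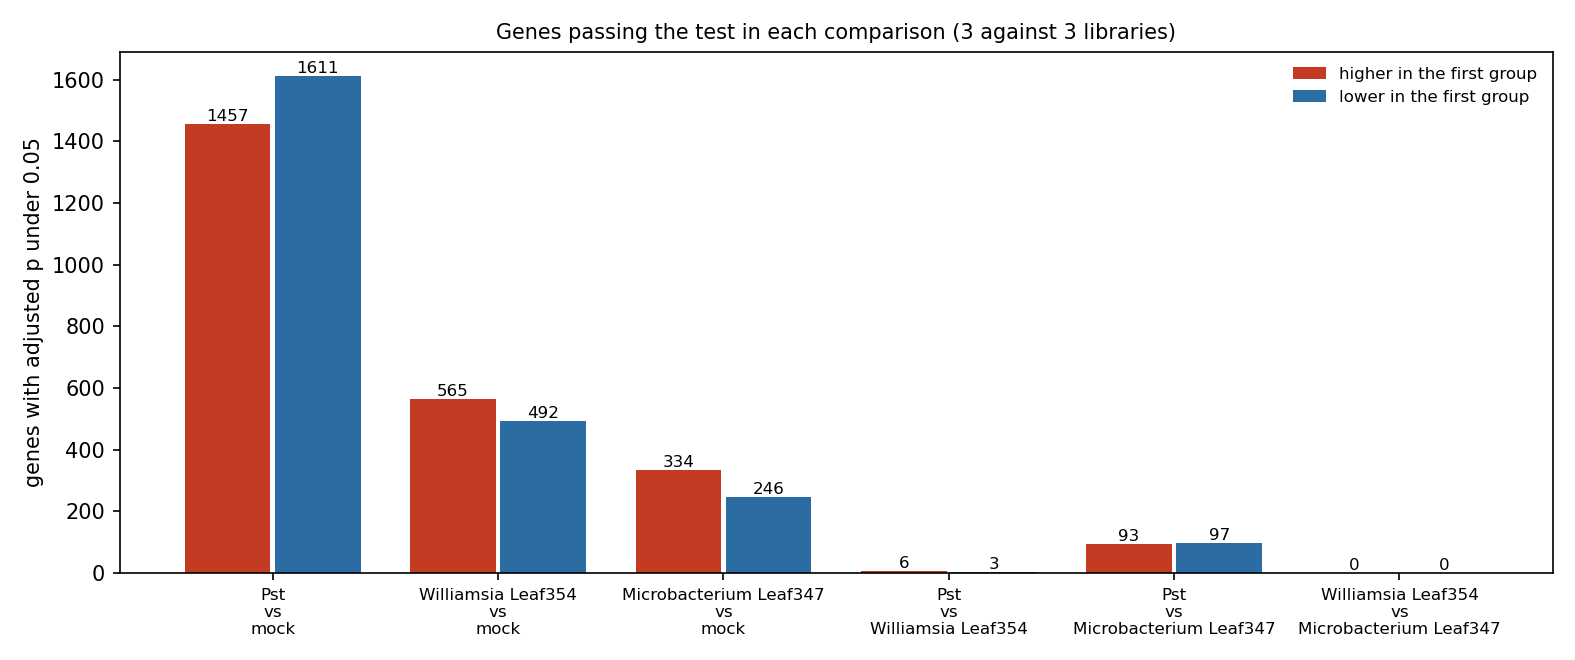
Number of genes called by edgeR in each of the 6 comparisons, higher and lower in the first group named. The counts are 3068, 1057 and 580 for Pst, Williamsia and Microbacterium against mock, and 9, 190 and 0 between the bacterial treatments.

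The comparison of Williamsia with mock asked for the response to an inoculated leaf isolate. AT1G80440 rose by 4.70 ± 0.40 on the log2 scale, from 4.63 ± 2.71 to 119.4 ± 20.8 CPM (mean ± SD, n = 3). TPS8 rose by 4.22 ± 0.28 and AT5G61590 by 3.85 ± 0.47. Among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, the lowest values were those of AT4G27657, at -2.81 ± 0.43, and AT1G24580, at -2.78 ± 0.40. RHA2A changed by -2.38 ± 0.21. EBF1 changed by -1.71 ± 0.15 and EBF2 (AT5G25350) by -0.99 ± 0.11, and both encode F-box proteins of ethylene signalling. EdgeR called 1057 genes, 565 higher and 492 lower, with 3762 at an unadjusted p under 0.05 and 297 changed by at least 2-fold. The count was 566 without mock replicate 1, 624 without mock replicate 3, 467 without Williamsia replicate 2 and 575 without Williamsia replicate 3. None of the 11 defence markers passed by edgeR, DESeq2 or limma-voom, with PR1 at -0.85 ± 0.40 (edgeR adjusted p = 0.275), and LOX2 passed only without mock replicate 3 (adjusted p = 0.0241).

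Lists in the comparison of Williamsia with mock were called with few of their genes called. In the jasmonic acid list JAZ7, at 1.68 ± 0.39 (SE, n = 3 per group), was the only gene of 30 called, also when adjusted over the list alone. Its adjusted p was 0.0997 and 0.0665 without mock replicates 1 and 2, and 0.0706 and 0.0704 without Williamsia replicates 1 and 2. Camera placed that list up (adjusted p = 0.00135, median 0.41), with adjusted p = 0.951 with an estimated correlation and 0.11 without mock replicate 2. The mean of the list was 0.19 in mock replicate 3, above Williamsia replicates 1 (-0.12) and 3 (-0.24), and -0.75 and -0.99 in mock replicates 1 and 2. Photosynthesis had 2 of 43 genes higher, PSAD2 and LHCB2.3, and 2 when adjusted over the list alone. PSAD2 was not called without mock replicates 2 and 3 (adjusted p = 0.0536 and 0.0627) or Williamsia replicate 2 (0.0867). LHCB2.3 was not called without mock replicates 1, 2 and 3 (0.0827, 0.0991 and 0.0718), Williamsia replicates 1 and 2 (0.0876 and 0.145) or Microbacterium replicate 3 (0.0541). Camera placed the photosynthesis list up (adjusted p = 0.000223, median 0.13), with adjusted p = 0.951 with an estimated correlation and 0.0722 without mock replicate 2. Its mean was -0.13 in Williamsia replicate 3, below mock replicates 1 and 3 (both -0.08), and -0.26 in mock replicate 2. In the iron list BTS rose by 0.81 ± 0.16, 1 of 2 called of 15, with 3 called when adjusted over the list alone (camera up, adjusted p = 0.00611, median 0.45, and 0.951 with an estimated correlation). The other, BHLH101 (AT5G04150), overlaps a gene with more reads, and it was not called without mock replicates 1 and 2 (0.121 and 0.0919), Williamsia replicates 1 and 3 (0.104 and 0.0705) or Microbacterium replicate 1 (0.0508). In the cell division list 1 of 23 genes was called, RNR2A, which overlaps a gene with more reads and whose adjusted p was 0.05 without Williamsia replicate 2 (camera up, adjusted p = 0.000309, median 0.35, and 0.951 with an estimated correlation). The mean of the cell division list was 0.10 in mock replicate 2, above Williamsia replicate 1 (0.003), and -0.40 and -0.50 in mock replicates 1 and 3. In the ethylene list 0 genes were higher and 2 lower, EBF1 and EBF2, with 3 of 17 called when adjusted over the list alone. Its median was 0.46 although camera placed it down (adjusted p = 0.756).

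The comparison of Microbacterium with mock asked the same of a further leaf isolate. AT1G80440 rose by 4.49 ± 0.40, from 4.63 ± 2.71 to 103.5 ± 14.8 CPM (mean ± SD, n = 3), and TPS8 by 4.03 ± 0.28. AT5G61590 was 13.9-fold higher, at 32.2 ± 2.89 against 2.31 ± 0.66 CPM. AT1G06980 changed by -2.37 ± 0.20, RHA2A by -1.87 ± 0.21, EBF1 by -1.30 ± 0.15 and EBF2 by -0.82 ± 0.11. EdgeR called 580 genes, 334 higher and 246 lower, with 3425 at an unadjusted p under 0.05 and 194 changed by at least 2-fold. DESeq2 called 1108. The edgeR count was 296 and 295 without mock replicates 1 and 3, and 203, 320 and 196 without Microbacterium replicates 1, 2 and 3. None of the 11 defence markers passed by edgeR, DESeq2 or limma-voom. PR1, at -1.14 ± 0.41 (adjusted p = 0.157), passed without Microbacterium replicate 1 (adjusted p = 0.0409), and LOX2 passed without mock replicate 3 (adjusted p = 0.0394).

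In the jasmonic acid list JAZ7 rose by 2.06 ± 0.38 in Microbacterium (SE, n = 3 per group), the only gene of 30 called, with an adjusted p of 0.0634 without mock replicate 1. When adjusted over the list alone 6 were called, and camera placed the list up (adjusted p = 2.72e-06, median 0.51), with adjusted p = 0.951 with an estimated correlation. The mean of the list was 0.19 in mock replicate 3, above Microbacterium replicates 1 (0.02) and 2 (0.08), and -0.75 and -0.99 in mock replicates 1 and 2. MCM7 (AT4G02060), which overlaps a gene with more reads, was the only cell division gene called of 23, with 2 called when adjusted over the list alone (camera up, adjusted p = 1.56e-05, median 0.45, and 0.951 with an estimated correlation). MCM7 was not called without mock replicates 1 and 3 (0.131 and 0.141), Pst replicate 1 (0.0664), Williamsia replicates 1, 2 and 3 (0.0555, 0.0625 and 0.0592) or Microbacterium replicates 1, 2 and 3 (0.141, 0.131 and 0.0786). The mean of the cell division list was 0.10 in mock replicate 2, above Microbacterium replicate 3 (-0.11), and -0.40 and -0.50 in mock replicates 1 and 3. EdgeR called 0 of 43 photosynthesis genes (7 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom). Camera placed that list up (adjusted p = 0.0367, median 0.08), with adjusted p = 0.951 with an estimated correlation. Its camera value was 0.569 without mock replicate 2, 0.0552 and 0.055 without Pst replicates 2 and 3, and 0.357 and 0.22 without Microbacterium replicates 1 and 3. Its mean was -0.18 in Microbacterium replicate 2, below mock replicates 1 and 3 (both -0.08). EdgeR called 0 of 15 iron genes (3 at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma-voom), and 1 when adjusted over the list alone. Camera placed the iron list up (adjusted p = 0.0175, median 0.41), with 0.951 with an estimated correlation, 0.0642 without mock replicate 1 and 0.0936 without Microbacterium replicate 2. EdgeR called 0 of 28 cysteine-rich receptor-like kinase genes (4 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom). Camera placed them down (adjusted p = 0.0363, median -0.26), with 0.951 with an estimated correlation, 0.0576 and 0.115 without mock replicates 1 and 3 and 0.125 without Microbacterium replicate 3. Their mean was 0.04 in Microbacterium replicate 2, above mock replicate 2 (0.01).

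**Figure D3:**
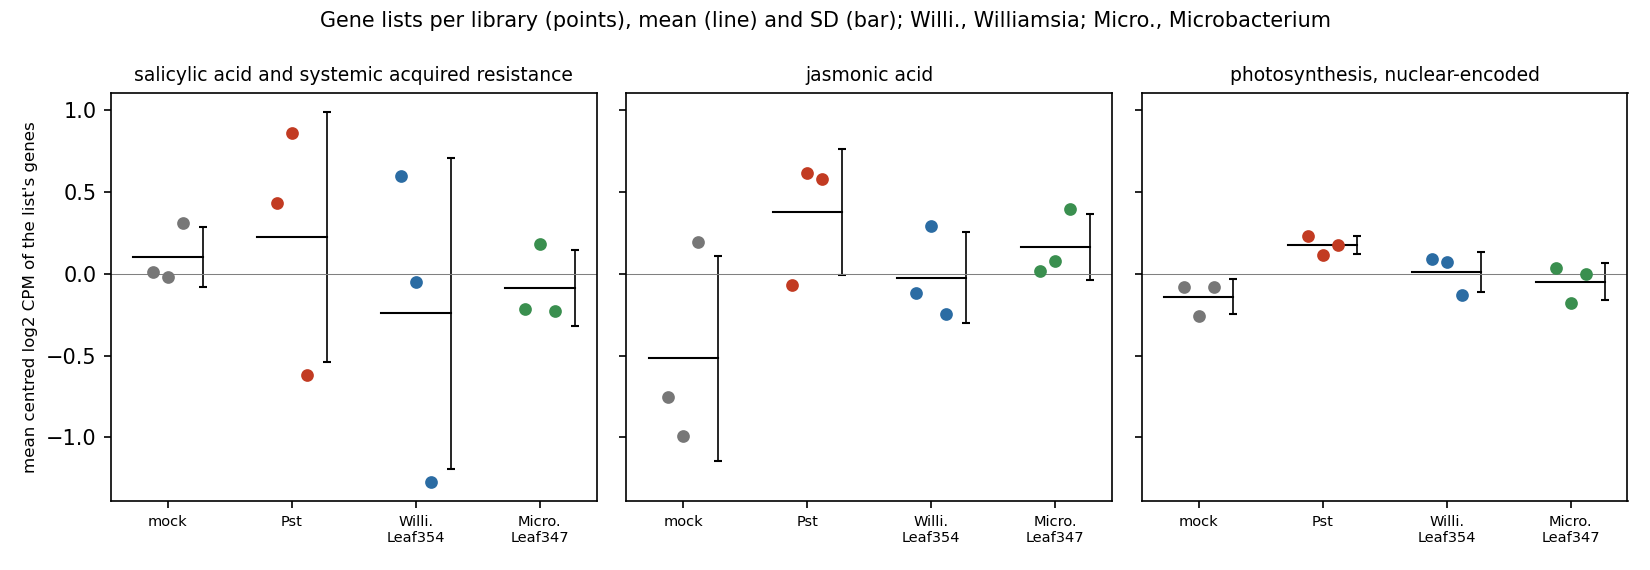
Mean log2 CPM, centred per gene, of the salicylic acid, jasmonic acid and photosynthesis lists in each library (points), with group means (lines) and SD (bars, n = 3). The salicylic acid list spans -0.62 to 0.86 among the Pst libraries and -1.27 to 0.60 among the Williamsia libraries.

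Whether the bacterial treatments changed the same genes was asked across the 19190 tested genes. Called in all 3 comparisons with mock, and in the same direction, were 473 genes, 287 higher and 186 lower, of 3176 called in at least 1 comparison. Besides AT1G80440, TPS8 and AT5G61590, those with the largest estimated shared changes were AT5G06865, AT3G15450, AT5G64190, AT1G23390, AT1G02610, AT1G06540 and AT5G14360. The AT5G06865 and AT1G06540 models lie over PGIP1 and PMD2, which are listed with 0 reads, and AT5G64190 overlaps a gene with more reads. The mock means of AT5G06865 and AT1G06540, 0.03 and 0.08 CPM, cannot be told from 0, so their ranks by log2 fold change are not measured. AT5G06865 was not called in Microbacterium without any single library other than Pst replicate 3 and Williamsia replicate 1 (adjusted p from 0.057 to 0.156), nor in Williamsia without mock replicates 1 and 3 (0.111 and 0.103) or Williamsia replicates 2 and 3 (0.102 and 0.0947). AT1G06540 was not called in Williamsia without Williamsia replicate 3 (0.0527), nor in Microbacterium without mock replicates 1 and 3 (0.0601 and 0.0669) or Microbacterium replicates 2 and 3 (0.0661 and 0.0786). Among the 473 genes, Pst had the largest absolute change in 341, and the median absolute log2 fold change was 1.04 in Pst, 0.88 in Williamsia and 0.79 in Microbacterium. No gene was called in opposite directions by edgeR with all groups fitted together and no covariate, while 1 was by DESeq2, 1 by edgeR with only the 2 groups compared in each fit, and 1 by edgeR with a surrogate variable. The shared count was 838 by DESeq2. It was 266 and 257 without mock replicates 1 and 3, 285 without Williamsia replicate 2, and 187, 292 and 178 without Microbacterium replicates 1, 2 and 3.

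Of the genes called for Williamsia, 92.9% were also called for Pst in the same direction (527 higher, 455 lower), against 42.9 and 41.3 for independent lists. Of those called for Microbacterium, 90.5% were also called for Pst (303 higher, 222 lower, against 25.4 and 20.7). Williamsia and Microbacterium shared 299 higher and 196 lower genes (against 9.83 and 6.31). The 3 comparisons use the same mock libraries, so part of the excess may come from the shared control. Across genes, the log2 fold changes correlated at r = 0.798 ± 0.118 for Pst and Williamsia (jackknife SE), 0.741 ± 0.116 for Pst and Microbacterium, and 0.807 ± 0.127 for Williamsia and Microbacterium. Without any response, simulated counts gave a mean r of 0.493, 0.496 and 0.493 and shared calls of 0 in each of 20 simulations. Genes were drawn independently in these simulations, so they do not show how many shared calls the mock libraries alone give where genes correlate. The covariance was 0.169, 0.150 and 0.135 in the data against 0.0347, 0.0347 and 0.0344 in the simulations. In 100 random draws of the residuals, the largest r was 0.846, 0.827 and 0.937, above the values of the data, while the largest covariance was 0.0995, 0.0908 and 0.0953, below the 0.155, 0.137 and 0.123 measured on the same scale. The residual draws keep the correlation between genes, but shared calls were not counted in them.

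**Figure D4:**
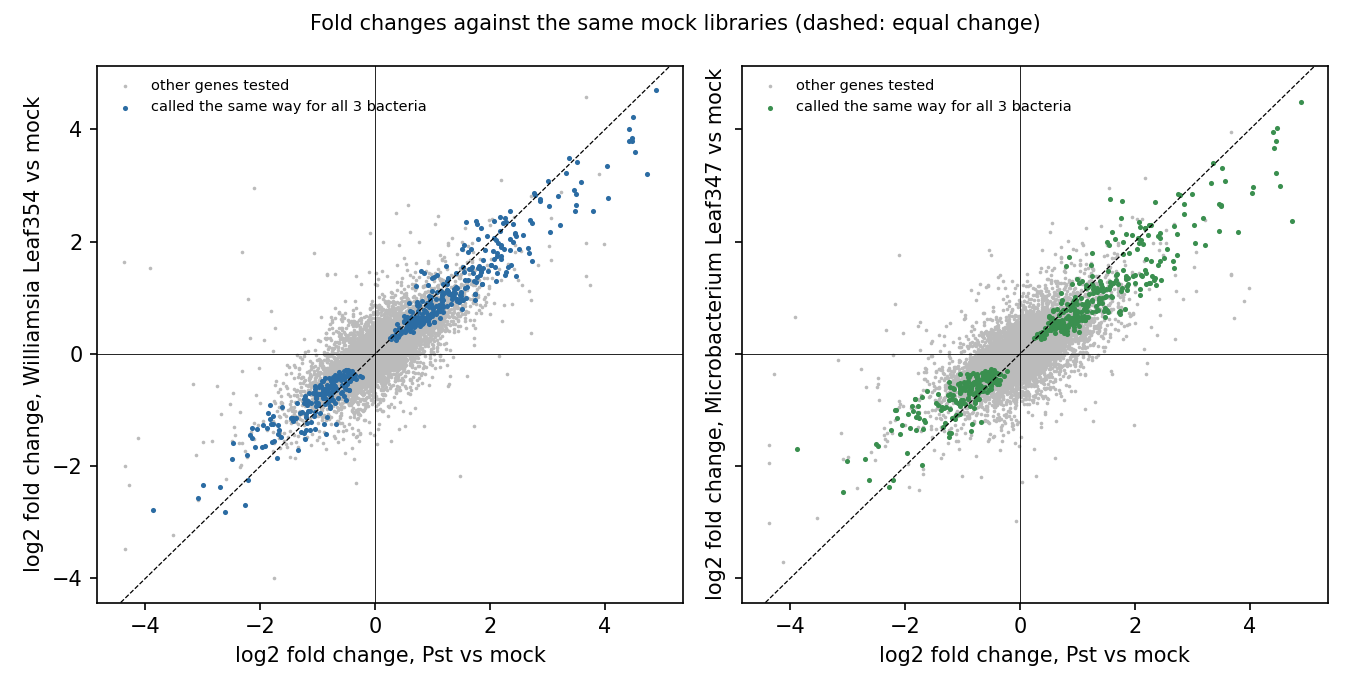
Log2 fold change against mock of each tested gene in Pst (horizontal) against that in Williamsia or Microbacterium (vertical), with a dashed line for equal change. The 473 coloured genes were called in the same direction in all 3 comparisons with mock, and in 341 of them the absolute change was largest in Pst.

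Direct comparisons asked which genes differed between bacterial treatments. Against Williamsia, Pst plants had 5.71-fold higher GA3OX1 (AT1G15550), a gibberellin 3-oxidase gene, at 11.7 ± 2.79 against 2.04 ± 0.79 CPM (mean ± SD, n = 3), a log2 difference of 2.51 ± 0.33 (SE). ARR7 (AT1G19050), a type-A response regulator gene of cytokinin signalling, was higher by 1.63 ± 0.22, ACR4 (AT1G69040) by 1.41 ± 0.17 and EBF2 by 0.76 ± 0.11. AT3G23080 and AT3G10405 were also higher, and both overlap other genes. AT2G24420, AT1G68440 and AT2G15020 were lower. These 9 genes were all that edgeR called (adjusted p between 0.0251 and 0.0393), with no overlap between the 3 libraries of each group in any of the 9, and 1612 genes had an unadjusted p under 0.05. DESeq2 called 135 and limma-voom 11. EdgeR called 0 genes without mock replicate 1 and 0 without any single Pst or Williamsia library other than Pst replicate 3. It called 141 without Pst replicate 3, 4 and 3 without mock replicates 2 and 3, and 4 and 5 without Microbacterium replicates 1 and 3. A fit of only these 2 groups called 0.

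EdgeR called 0 genes of the jasmonic acid and photosynthesis lists between Pst and Williamsia (2 and 9 at an unadjusted p under 0.05, 0 by DESeq2 and by limma-voom). Camera placed both lists higher in Pst, jasmonic acid at a median of 0.44 (adjusted p = 2.4e-05) and photosynthesis at 0.17 (adjusted p = 2.19e-11), with adjusted p = 0.951 for both, and for the other 4 lists called, with an estimated correlation. It also placed up the salicylic acid list (median 0.34, adjusted p = 0.00921), which gave 0.0849 and 0.858 without Pst replicates 1 and 2 and reversed without Williamsia replicate 3 (0.975). The camalexin list (median 0.26, adjusted p = 0.0363) gave 0.828 without Pst replicate 2 and 0.486 without Williamsia replicate 3. The cell division list was placed lower in Pst (median -0.18, adjusted p = 0.0327), with 0.104 and 0.465 without Pst replicates 1 and 2 and 0.0577 and 0.2 without Williamsia replicates 2 and 3. The clock list was placed lower too (median -0.10, adjusted p = 0.0388). It gave 0.0591 without mock replicate 2, 0.0917 and 0.0732 without Pst replicates 1 and 2, 0.0547, 0.0533 and 0.0517 without Williamsia replicates 1, 2 and 3, and 0.0514 without Microbacterium replicate 1.

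Against Microbacterium, Pst plants also had higher GA3OX1, by 3.10 ± 0.34, and ARR7, by 2.36 ± 0.23 (SE, n = 3 per group). AT5G66052 was lower by -2.09 ± 0.27, at 3.87 ± 0.97 against 16.5 ± 4.66 CPM (mean ± SD). ARR15 (2.16) and ARR6 (1.88) were higher, as were GA20OX1 (2.04), BBX17 (2.82) and BBX14 (1.53). The adjusted p was 0.0656 for ARR15 without Microbacterium replicate 3, and 0.0522 and 0.0606 for GA20OX1 without Microbacterium replicates 2 and 3. It was 0.0502 for ARR6 and 0.0541 for BBX17 without Pst replicate 1, and the BBX14 call was lost in a fit of only the 2 groups (0.0551). EdgeR called 190 genes, 93 higher and 97 lower in Pst, with 2642 at an unadjusted p under 0.05 and 51 changed by at least 2-fold. DESeq2 called 558 and a fit of only these 2 groups 54. The edgeR count was 37, 81 and 673 without Pst replicates 1, 2 and 3, 87, 34 and 37 without Microbacterium replicates 1, 2 and 3, and 124 without Williamsia replicate 2.

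Camera placed photosynthesis higher in Pst than in Microbacterium (median 0.23, adjusted p = 2.26e-14), with adjusted p = 0.951 with an estimated correlation, as for the other 6 lists called. EdgeR called 0 of its 43 genes (26 at an unadjusted p under 0.05, 7 by DESeq2, 0 by limma-voom), and 13 when adjusted over the list alone. The clock list was placed lower (median -0.22, adjusted p = 0.00836), with PRR9 the only 1 of 13 called and 4 when adjusted over the list alone. PRR9 was not called without mock replicate 3 (0.056), Pst replicates 1 and 2 (0.176 and 0.127), Williamsia replicates 1, 2 and 3 (0.0518, 0.0643 and 0.0579) or Microbacterium replicates 1, 2 and 3 (0.0858, 0.157 and 0.117). The salicylic acid list was placed up (median 0.49, adjusted p = 0.0367), with 0.118 and 0.878 without Pst replicates 1 and 2 and 0.164 and 0.123 without Microbacterium replicates 1 and 3. The cysteine-rich receptor-like kinases (median 0.28, adjusted p = 0.023) gave 0.101 and 0.649 without Pst replicates 1 and 2 and 0.0525 and 0.123 without Microbacterium replicates 1 and 3. The jasmonic acid list (median 0.34, adjusted p = 0.0406) gave 0.31 and 0.359 without Pst replicates 2 and 3 and 0.228 without Microbacterium replicate 1. The heat shock list (median 0.49, adjusted p = 0.0326) gave 0.409 and 0.142 without Pst replicates 1 and 3 and 0.251 without Microbacterium replicate 1. The cell division list was placed down (median -0.24, adjusted p = 0.0367), with 0.103 and 0.363 without Pst replicates 1 and 2 and 0.506 without Microbacterium replicate 2.

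Between Williamsia and Microbacterium edgeR called 0 genes, with 520 at an unadjusted p under 0.05. DESeq2 called 0 (474 unadjusted) and limma-voom called 0 (508 unadjusted). Camera placed photosynthesis higher in Williamsia at a median of 0.06 (adjusted p = 0.00318, and 0.951 with an estimated correlation). That adjusted p was 0.439 and 0.241 without Williamsia replicates 1 and 2, and the direction reversed without Microbacterium replicate 2 (0.864). The senescence list was placed up (median 0.24, adjusted p = 0.018, and 0.951 with an estimated correlation), with 0.633 without Williamsia replicate 3 and 0.226 without Microbacterium replicate 2. The absence of a call does not show that both treatments had equal effects.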

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

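The lists compared here across libraries were chosen only after the result was seen. The direct comparisons drew attention because they test the difference between bacterial treatments itself. EdgeR called 9 genes between Pst and Williamsia, with GA3OX1 higher in Pst by 2.51 ± 0.33 (log2, SE), and 190 genes between Pst and Microbacterium, with GA3OX1 higher by 3.10 ± 0.34. A split of 3 libraries against 3 can be made in 10 ways, too few for a share under 0.05. As many genes were called in 2 of the 10 splits between Pst and Williamsia (9 in the real split, 180 at most in another) and in 1 of 10 between Pst and Microbacterium (190 in the real split, 0 at most in another). The split with 180 genes set Pst replicates 1 and 2 and Williamsia replicate 1 against the other 3 libraries, which points to a structure of the samples that crosses the treatments.

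Pst replicates 1 and 2 and Williamsia replicate 1 also lay above the other 3 libraries in the salicylic acid list (0.43, 0.86 and 0.60 against -0.62 in Pst replicate 3 and -0.05 and -1.27 in Williamsia replicates 2 and 3, mean log2 CPM centred per gene). The phosphate starvation list divided them in the same way (0.19, 1.11 and 0.96 against -0.58, -0.50 and -0.33). Wide spread within groups was not particular to defence genes, since the phosphate list ran from -1.02 to 0.82 in mock and the senescence list from -0.50 to 1.15 in Williamsia. The correlation of library size with the salicylic acid list over the 12 libraries left open whether size contributed to the spread (absolute r = 0.333, r = -0.333, permutation p = 0.29, rho = -0.259, permutation p = 0.417, and r = -0.302 without the 2 libraries farthest from the median). The sizes themselves argue against it for these libraries. Log2 totals lay between -0.063 and 0.045 from their group means. The list, already scaled to library size, lay between -1.03 and 0.84 from its group means. Different progress of the response in plants of 1 treatment, or different boxes, stays open, and no biological explanation was tested.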

How the results depend on the processing

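The surrogate variable was a test chosen only after the result was seen. Counts of called genes stayed within 1.5 times the reported value for every comparison under RLE and upper-quartile scaling, no filter, the CPM filter, limma-voom, removal of organelle genes and the surrogate variable. The correlations between responses moved by less than their jackknife SE under RLE scaling, the replicate block and a limit to genes with a mean log2 CPM of at least 1. Leaving out each library gave r from 0.706 to 0.824 for Pst and Williamsia, and from 0.649 to 0.777 for Pst and Microbacterium. For Williamsia and Microbacterium it gave 0.715 to 0.833. The jackknife SE is computed from these same values, so it cannot judge them. The other counts are given below, and the cause of their change was not tested. Some of these alternatives use fewer libraries or set a stricter threshold. For Pst against mock the count was 1928 with only the 2 groups and 640 at 2-fold, and for Williamsia against mock it was 297 at 2-fold. For Microbacterium against mock it was 1108 by DESeq2 and 194 at 2-fold. For Pst against Williamsia it was 135 by DESeq2, 0 with the replicate number as a block, 0 with only the 2 groups and 3 at 2-fold. For Pst against Microbacterium it was 558, 54 and 51 by DESeq2, with only the 2 groups and at 2-fold. DESeq2 gave 2520 genes among the 4 groups and 838 shared genes. Leaving out 1 library in turn gave 2069 to 3098 genes for Pst, 467 to 1321 for Williamsia and 196 to 867 for Microbacterium against mock, 0 to 141 between Pst and Williamsia, 34 to 673 between Pst and Microbacterium, 940 to 1937 among the 4 groups, and 178 to 677 shared. Of 150 list tests 28 were called, 0 with an estimated correlation, 0 by directional fry, 19 by mixed fry, and 23 to 56 without 1 library (56 without Williamsia replicate 1, 47 without mock replicate 3). The salicylic acid list between Pst and Williamsia reversed without Williamsia replicate 3 (adjusted p from 4.85e-10 to 0.975 over the libraries left out), and photosynthesis between Williamsia and Microbacterium reversed without Microbacterium replicate 2 (from 8.81e-11 to 0.864). The 2-fold threshold was left out when the stability of named genes was counted. Of 55 named genes called for Pst against mock, 44 were called under every other alternative. The number called under all of these was 23 of 40 for Williamsia and 17 of 31 for Microbacterium. Between Pst and Microbacterium it was 3 of 24, ARR7, GA3OX1 and AT5G66052, and between Pst and Williamsia it was 0 of the 9 genes called. The residuals of libraries with the same number correlated between -0.194 and 0.182 across genes, over 0.1 in 4 of 18 pairs, against -0.219 to 0.239 for other pairs. Closest to a library of their own number were 7 of 12, not all, so the numbers were not taken to pair the libraries, and the block fits are only a hint. At these totals, genes with a CPM under about 0.15 cannot be told from 0.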

Other observations

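The lists in this part, the 95% intervals and the medians in Williamsia and Microbacterium used to judge the dark and touch lists, and the random draws of residuals in the report were tests chosen only after the result was seen. The sulfur, cytokinin, gibberellin and B-box lists were made because some of their genes had been seen among the largest changes, so only counts are given for them and no test of the list as a whole. Of 11 tested genes of the O-acetylserine cluster and of sulfur limitation, 7, 6 and 6 were called higher against mock in Pst, Williamsia and Microbacterium and 0 lower, with medians of 1.17, 1.51 and 1.34. SDI1 rose by 2.15 in Pst, 2.43 in Williamsia and 2.29 in Microbacterium, and SHM7 rose by 2.36 in Williamsia and 2.35 in Microbacterium (log2). Of 8 type-A cytokinin response regulator genes, 6 were higher and 1 lower against mock in Pst, 0 higher and 2 lower in Williamsia, and 0 higher and 1 lower in Microbacterium. Compared directly, edgeR called 5 of 8 higher in Pst than in Microbacterium (in either direction 6 by DESeq2, 5 by limma-voom and 8 at an unadjusted p under 0.05). Against Williamsia it called 1 of 8, ARR7 (in either direction 5 by DESeq2, 1 by limma-voom and 7 unadjusted), so the counts do not show that the comparisons differ. ARR7 was not called without any single library other than Pst replicate 3 and Microbacterium replicates 1 and 2 (adjusted p from 0.0516 to 0.143).

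Among 13 gibberellin synthesis and DELLA genes, 4 were higher and 4 lower in Pst, 0 higher and 4 lower in Williamsia, and 0 higher and 3 lower in Microbacterium. GA3OX1 rose by 3.73 ± 0.36 in Pst, and GA20OX1 by 2.38 ± 0.31. GAI, a DELLA repressor gene of growth, changed by -1.67 ± 0.15, -1.36 ± 0.15 and -1.18 ± 0.15 in Pst, Williamsia and Microbacterium. RGL3, also a DELLA gene, was higher in Pst, and its call was lost without mock replicates 1 or 3 or Pst replicates 2 or 3 (adjusted p up to 0.0912 over the alternatives). The 17 tested B-box transcription factor genes moved both ways, 5 higher and 10 lower in Pst, 3 and 5 in Williamsia, and 2 and 2 in Microbacterium.

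TPS8 and BBX14, picked because genes of their families respond to carbon or light, were higher than in mock in all 3 treatments. TPS8 rose by 4.48, 4.22 and 4.03 and BBX14 by 4.53, 3.61 and 3.00 in Pst, Williamsia and Microbacterium (log2). The values at hand exclude none of 3 handling explanations, since harvest order and time are not given in the labels. A different time of day may contribute. The clock genes had a median absolute log2 fold change of 0.479 in Pst, above the 0.378 of the 95th percentile of 10000 random lists, and of 0.27 in Williamsia and 0.30 in Microbacterium. Morning and evening genes had medians of -0.48 and -0.21 in Pst, -0.28 and -0.09 in Williamsia, and -0.25 and 0.17 in Microbacterium, so they went in opposite directions only in Microbacterium. Darkness or a lack of sugar may contribute too. The 18 tested genes that these conditions induce had a median of 0.197 in Pst (95% interval -0.043 to 0.345), 0.067 in Williamsia (-0.061 to 0.369) and -0.12 in Microbacterium (-0.203 to 0.261). Genes picked from the result, such as TPS8 and BBX14, were left out of this list and of the touch list below, so the medians do not cover them. The Pst median lay above the 0.119 of the 95th percentile of 10000 random lists, which were drawn for Pst only. Camera placed the list up in Pst (adjusted p = 0.0343 over 36 tests, 0.579 with an estimated correlation), with 0.0951 and 0.116 without mock replicates 1 and 2 and 0.0752 without Pst replicate 2. It gave 0.0994 in Williamsia and 0.792 in Microbacterium, where TPS8 and BBX14 were also higher. Longer touching of mock plants may contribute as well. The 15 tested touch- and wound-induced genes had a median of -0.0125 in Pst (95% interval -0.854 to 0.437), 0.106 in Williamsia (-0.356 to 0.542) and 0.163 in Microbacterium (-0.271 to 0.521). Their members went both ways, from -4.36 to 1.25 in Pst, from -3.49 to 1.51 in Williamsia and from -1.95 to 1.54 in Microbacterium, and 3, 2 and 0 were called lower. For both lists the medians lay past the bound set beforehand in Pst for rejecting the explanation, in the direction that goes against it. The Pst median of the dark and sugar list did so only narrowly. No interval lay wholly past its bound, so neither explanation was rejected. A response of the plants to bacteria remains the explanation the design names, and it was not separated from these.

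Other splits of the libraries were counted for the remaining comparisons. With 10 splits a share under 0.05 cannot be reached. As many genes as in the real split were called in 1 of 10 splits for Pst against mock (3068 in the real split, 0 at most in another), in 1 of 10 for Williamsia against mock (1057 and 0), and in 1 of 10 for Microbacterium against mock (580 and 0). For Williamsia against Microbacterium the real split called 0 genes (2 at most in another). Every split reaches a count of 0, so the splits cannot judge that comparison. For the test among the 4 groups 1 of 100 splits, the real one, gave as many genes (1657, with 764 at most in another). Chance is therefore unlikely for that count but not excluded. The splits do not test differences in boxes or handling that coincide with the groups.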
